A study of Sus scrofa with 6 samples.

How the data were processed

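Total RNA of 6 pig samples was measured by RNA sequencing: 2 libraries of a line of expanded potential stem cells (EPSC) from cloned embryos, 2 of cloned blastocysts on day 7 and 2 of a line of induced pluripotent stem cells (iPSC). Per the labels' protocols, RNA was isolated with RNAiso Plus, 10 ng of total RNA went into each library, and libraries were made with a stranded total RNA kit for low input (SMARTer Stranded Total RNA-Seq, V2, Pico) for paired-end reads of 151 bp. Per the submitters' processing notes, the authors used cutadapt 2.8 and STAR 2.7.1a with the pig genome Sscrofa11.1. The deposited count table holds raw read counts per Ensembl gene, whole numbers that sum to a different total in each library, per the file headers and the values. The deposited FPKM table holds the authors' FPKM of the same genes to 2 decimals, per the file headers. The program that counted the reads, its strand setting, its treatment of reads with several matches, the annotation release and the program that made the FPKM were not given in the sources used here. Counts of genes that overlap another gene, of nuclear copies of mitochondrial genes and of genes with near-identical copies are therefore uncertain.

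The count table holds 31885 genes, of which 22093 had a read in some library. In 5710 of 191310 cells the count was written with a comma between digits, which was removed, and every value was then a whole number. Symbols came from the count table for 16679 genes, from a gene ID table for 797 and from a RefSeq table for 790, and 13619 genes had none. 86 symbols were held by more than 1 gene, and for 551 genes symbol and description disagreed. An overlapping gene lay on the same strand for 5472 genes and on the opposite strand for 8800. Coordinates are those of the deposited table, on Sscrofa11.1, counted from 1.

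Genes were kept for testing with a CPM of at least 1.94925 in 2 libraries, which is a count of 10 at the median depth, and a total of at least 15 reads, which left 14397. Library sizes were scaled by TMM. Differences were tested with limma-voom with robust empirical Bayes moderation, in 1 fit of all 6 libraries with 3 groups and 3 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05, separately for each of 3 comparisons. A quasi-likelihood count model had been planned, and limma-voom took its place because the cells written with commas failed a check of the count unit, although their values are raw counts. The comparisons, 27 gene lists, rule for named genes and the first set of alternatives below, except treat, were chosen before the data were examined. Another 8 lists and the genes said to be chosen after their values were seen were not. Limma-voom, camera on its fit and treat took the place of planned tests after the count table had been read.

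Lists of at least 5 tested genes were tested with camera, with a preset correlation of 0.01, and p-values were adjusted over the 27 lists, and again over the 8 later lists. Camera with an estimated correlation and fry, which asks if the genes of a list move one way on balance and compares them with no other genes, were alternatives. With the estimated correlation no list of the 27 was called in any comparison. That alternative rests on the 3 residual degrees of freedom, so a lost call does not by itself mean correlated genes. In EPSC against blastocyst the trophoblast list lost its call (adjusted p = 0.181) at an estimated correlation of -0.0143, below the preset. In the simulation for that comparison, 20 independent genes raised 2-fold went from camera adjusted p = 4.32e-51 to 0.0169. A gene could be named if it had a symbol, passed the test, had a mean of at least 5 CPM in the group where it was higher, and both libraries of one group lay above both of the other. Of each list, in order of camera p, up to 4 such genes with the largest fold change were taken, at most 2 against the direction of the list, until about 30 were named, and then the 5 highest and 5 lowest of all such genes. A further 13 genes, among them POU5F1, NANOG, CDX2 and GATA6, were named in every comparison. Folds of genes with 1 to 3 counts in a group are ratios of pooled counts with a 95% counting interval.

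The total count per library ran from 3459271 to 6310751. On the TMM-scaled library sizes 3 counts, the limit that a count of 0 allows, stood for 0.434 to 0.762 CPM. Over genes with enough reads, the chi-square per degree of freedom between the 2 libraries was 4.95 in blastocyst, 2.96 in iPSC and 2.32 in EPSC, so no pair agreed within sampling noise. The tests were tested on simulated counts with 200 changed genes. In the data 73.5%, 64.5% and 72.3% of the tested genes were called in the 3 comparisons. The simulation therefore does not test the scaling or the error rates where most genes change. For EPSC against blastocyst, limma-voom called 66.7% of genes changed 2-fold and 95.9% of those changed 4-fold, with 11 calls on unchanged genes among 13520. For EPSC against iPSC the shares were 69.4% and 87.8%, with 15 calls among 13544, and for iPSC against blastocyst 55.9% and 91.8%, with 7 among 13519. Of 26 unchanged lists camera called 0, 2 and 1. The simulated genes varied independently, so these lists do not test camera where the genes of a list are correlated. In the data the estimated correlation of the mitochondrially encoded list was 0.795 in EPSC against iPSC.

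Alternatives were median-of-ratios scaling, no filter and another filter on low counts, the replicate number as a block, a fit of only the groups compared, a test against a log2 fold change of 1 (treat), limma-trend on the deposited FPKM with pseudocounts of 1 and 0.1 and with a minimum mean of 1, leaving out the 50 most abundant genes, thinning to 3459271 counts and leaving out each replicate. Added after the data were seen were limma-trend on log2 CPM, a filter of a mean of 5 CPM and a test of nuclear protein-coding genes only. For shared controls, 20 sets of unchanged lines and blastocyst libraries were simulated, all at the mean level of the blastocyst libraries. List medians were set against 10000 random lists matched on transcript length and mean expression. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.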

Results

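RNA from pig cells and embryos was sequenced in 6 libraries that fell into 3 groups of 2. The first group was a line of expanded potential stem cells (EPSC), a type of stem cell line, which the labels trace to cloned embryos. The second was blastocysts on day 7 after cloning by somatic cell nuclear transfer, and the third was a pig line of induced pluripotent stem cells (iPSC). Total counts assigned to genes were 6101276 and 3459271 in the EPSC libraries, 5744005 and 6310751 in the blastocyst libraries and 3988645 and 4516360 in the iPSC libraries. Genes with at least 1 read numbered 17352 and 16805 in EPSC, 17754 and 17406 in blastocyst and 15040 and 15104 in iPSC. Replicates of a group are named as such in the labels, which do not say whether they came from separate cultures or pools of embryos, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as CPM, read counts scaled to TMM library sizes, as mean ± SD over n = 2 libraries per group. A fold against a group with no read is a lower bound set at 3 counts over that group. Floors and counting intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

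The 3 groups lay far apart and the replicates close together. The leading log2 fold change distance, over the 500 genes that differed most in each pair of libraries, was 6.86 on average between groups (6.16 to 7.50) and 1.68 to 2.04 within groups. Across the 14397 genes tested, which are not independent replicates, Pearson's r of log2 CPM was 0.715 to 0.721 between EPSC and iPSC libraries, 0.605 to 0.616 between EPSC and blastocyst libraries and 0.598 to 0.605 between iPSC and blastocyst libraries. Shares of the reads also differed between groups. Genes of the mitochondrial genome took 5.08% and 4.59% of the counts in blastocyst, 4.00% and 3.90% in iPSC and 2.26% and 1.98% in EPSC. Signal recognition particle and other miscellaneous RNA genes took 2.42% and 2.54% in blastocyst, 0.451% and 0.504% in iPSC and 0.0876% and 0.0689% in EPSC.

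The pluripotency regulator POU5F1 was at 356 ± 16.1 CPM in EPSC and 203 ± 17.8 CPM in blastocyst, and had no read in either iPSC library. LIN28A, an RNA-binding protein of pluripotent cells, was at 698 ± 6.64 CPM in EPSC, 311 ± 6.58 CPM in blastocyst and 0.609 ± 0.862 CPM in iPSC. NANOG, another factor of that network, was at 17.5 ± 2.10 CPM in iPSC, 4.98 ± 0.938 CPM in EPSC and 5.82 ± 0.573 CPM in blastocyst. The trophoblast factor CDX2 was at 88.5 ± 26.5 CPM in blastocyst and had no read in either line. TBXT, a gastrulation marker, stayed below the filter for testing, with 0.0724 CPM in EPSC, 0 in iPSC and 1.75 CPM in blastocyst. SOX2 and XIST had no entry of their own under those symbols and were not analysed here.

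**Figure D1:**
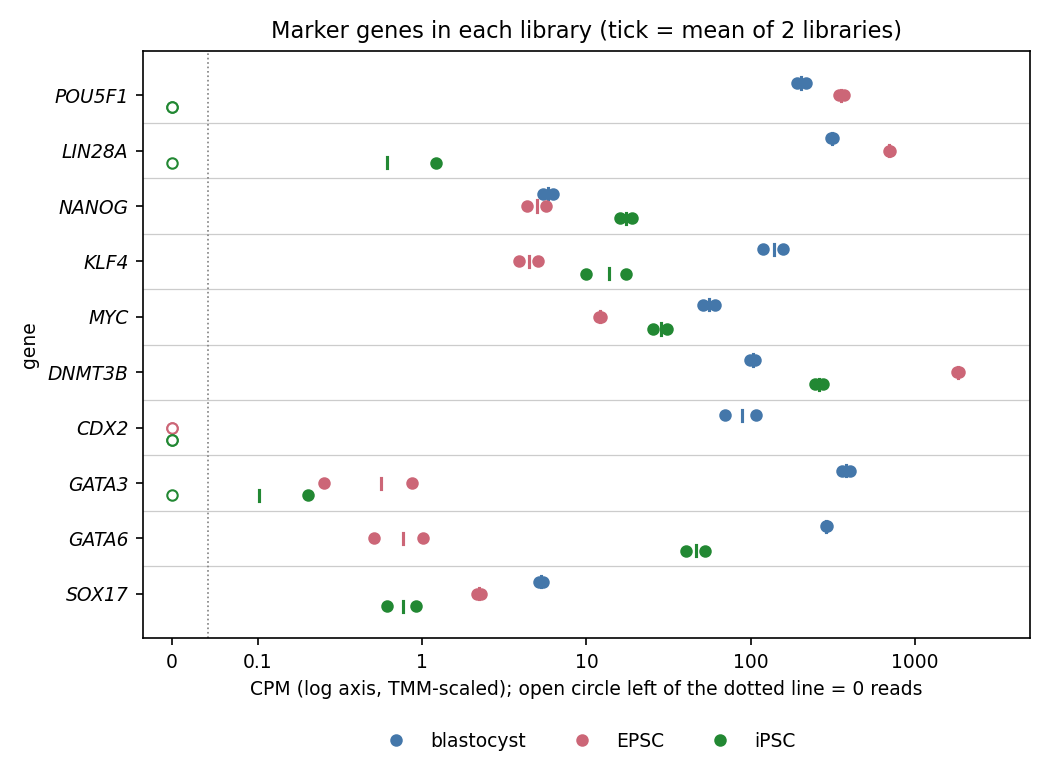
Each point is the TMM-scaled CPM of 1 library on a log axis, coloured by group, for 10 marker genes, and each tick is the mean of the 2 libraries of a group. Open circles left of the dotted line are libraries with 0 reads. Among them, POU5F1 has none in either iPSC library, CDX2 none in either line, and LIN28A and GATA3 none in a single iPSC library each.

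The first comparison set the EPSC line against cloned blastocysts, the kind of embryo that the labels name as its origin. All 20 tested genes of the trophoblast list fell (camera adjusted p = 1.20e-08, and adjusted p = 0.181 with an estimated correlation), and all 15 tested genes of the primed epiblast list rose (camera adjusted p = 2.57e-08, and adjusted p = 0.181 with an estimated correlation). PTGS2, a prostaglandin synthase (ENSSSCG00000015579, chromosome 9, 127850013 to 127858884, minus strand), was 6422-fold lower, from 1913 ± 7.30 to 0.290 ± 0.409 CPM. A single EPSC library held all of its EPSC reads, so the size of that fold is uncertain. DNMT3B, a de novo DNA methyltransferase, was 17.8-fold higher, from 103 ± 4.99 to 1835 ± 28.3 CPM.

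Of 14397 genes tested, 5338 were higher and 5249 lower in EPSC than in blastocyst (limma-voom, Benjamini-Hochberg adjusted p under 0.05). On the deposited FPKM the split was 6925 higher and 3664 lower, or 65.4% higher against 50.4% on counts, and the median log2 fold change of all genes lay 0.352 higher than on counts. The FPKM were tested as deposited, without the TMM scaling of the counts. The TMM factors were 0.814 and 0.793 in blastocyst and 1.14 in each EPSC library, so leaving them out raises log2 fold changes. FPKM and counts also parted in EPSC, where 546 and 531 genes with no read had an FPKM above 0. Against a log2 fold change of 1, 2961 genes were higher and 2631 lower. The 49 called genes named by the rule had adjusted p between 1.83e-12 and 0.029 (limma-voom).

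In the trophoblast list the median log2 fold change was -8.76, and -7.90 with genes of at most 3 counts in a group set at a bound of 3 counts. GATA2, GATA3 and TFAP2C, transcription factors of the trophoblast, were 2570-fold (95% counting interval 879 to 12465), 618-fold and 1637-fold (95% counting interval 293 to 64701) lower. CDX2 (ENSSSCG00000009317, chromosome 11, 5339716 to 5346057, minus strand) was at least 322-fold lower. The naive and inner cell mass list fell as well, with 10 of 11 genes lower and 1 higher (camera adjusted p = 0.00269, and adjusted p = 0.317 with an estimated correlation). KLF17 and DPPA5, markers of naive pluripotency, were at least 124-fold and at least 86.1-fold lower, with no read in EPSC. TBX3 was 356-fold lower and TFCP2L1, a factor of the naive network, was 106-fold lower. KLF4 was 30.8-fold lower at 4.50 ± 0.830 CPM, and the proto-oncogene MYC 4.54-fold lower. The core pluripotency list was not called: 7 of 13 genes rose and 4 fell (camera adjusted p = 0.587). POU5F1 (ENSSSCG00000001393, chromosome 7, 23564659 to 23570600, minus strand, Sscrofa11.1) was 1.76-fold higher and LIN28A 2.25-fold higher, while NANOG, at -0.18 ± 0.40 (log2 fold change ± SE), did not pass (adjusted p = 0.692). The median of that list was 0.81 and its mean -0.72, with the test upward, and among its members ESRRB was 87.9-fold lower and DPPA2 at least 177-fold lower.

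The primed epiblast list had a median log2 fold change of 5.00. VRTN, a gene tied to vertebral number in pigs, was 659-fold higher (95% counting interval 182 to 5444), and SOX11, a transcription factor of epiblast and neural cells, 233-fold higher. The secreted WNT antagonists SFRP1 and SFRP2 were 155-fold and at least 131-fold higher. DNMT3B (ENSSSCG00000007252, chromosome 17, 36332801 to 36386074, plus strand) had a log2 fold change of 4.15 ± 0.08 (± SE). The list of DNA and histone methylation machinery rose, with 15 of 21 genes higher and 5 lower (camera adjusted p = 0.0182, and adjusted p = 0.263 with an estimated correlation). UHRF1, which recruits the maintenance methyltransferase, was 30.3-fold higher, DNMT1 3.18-fold higher and TET2, an enzyme that oxidises methylcytosine, 4.32-fold lower. FGF and ERK targets gave 11 of 17 genes higher, among them ETV5 (27.4-fold) and DUSP6 (10.2-fold), and 5 lower (camera adjusted p = 0.0443, and adjusted p = 0.515 with an estimated correlation). With the replicate number as a block that call ended (camera adjusted p = 0.0627).

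Genes of epithelial junctions fell in EPSC, with 21 of 24 lower, 1 higher and a median log2 fold change of -2.53 (camera adjusted p = 5.44e-09, and adjusted p = 0.212 with an estimated correlation). The desmosomal protein PKP3 was 99.8-fold lower and the tight junction claudins CLDN4 and CLDN7 45.8-fold and 19.9-fold lower. SPINT1, an inhibitor of epithelial surface proteases, was 24.7-fold lower, and CDH1, the epithelial cadherin, 5.59-fold lower but still at 393 ± 15.6 CPM. Of the blastocoel and ion transport list, 10 of 15 genes fell and 3 rose (camera adjusted p = 0.0206, and adjusted p = 0.263 with an estimated correlation), and ATP1A1, a subunit of the sodium pump, was 4.47-fold lower. The mesenchyme and fibroblast list rose in 10 of 17 genes and fell in 2 (camera adjusted p = 0.0308, and adjusted p = 0.406 with an estimated correlation). Among those higher were VIM, an intermediate filament also found in epiblast cells (38.8-fold), and MMP2, a matrix protease (38.4-fold). The fibroblast collagen COL3A1 had no read in EPSC, but other collagens of that list had reads there, at levels given further below.

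Of 34 nuclear genes of oxidative phosphorylation, 32 fell and 0 rose, with a median log2 fold change of -1.56 (camera adjusted p = 1.21e-10, and adjusted p = 0.181 with an estimated correlation). Random lists of the same size matched on transcript length and mean expression had a median of -0.49, and the libraries also differed in their mitochondrial and miscellaneous RNA shares as given above. ATP5MC1, subunit c of ATP synthase, was 6.86-fold lower, the electron carrier CYCS 5.18-fold lower, and the respiratory chain subunits NDUFB9 and NDUFA4 4.68-fold and 4.15-fold lower. All 13 protein-coding genes of the mitochondrial genome fell, with a median log2 fold change of -1.55 (camera adjusted p = 1.15e-07, and adjusted p = 0.406 with an estimated correlation). CYTB was 5.19-fold lower, ND3 3.60-fold lower, COX1 3.46-fold lower and ND4L 3.45-fold lower. Glycolysis genes rose in 12 of 20 and fell in 6 (camera adjusted p = 0.0410, and adjusted p = 0.454 with an estimated correlation), with PFKM, the muscle phosphofructokinase, 13.9-fold higher and PKM, the pyruvate kinase, 3.70-fold higher. Proliferation genes rose in 16 of 27 and fell in 5 (camera adjusted p = 0.00284, and adjusted p = 0.181 with an estimated correlation). MKI67 was 6.42-fold higher, the spindle checkpoint kinase BUB1B 4.61-fold higher, the replication helicase subunit MCM5 3.70-fold higher and the mitotic kinase AURKB 3.68-fold higher.

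Of the p53 targets 12 of 17 fell and 2 rose (camera adjusted p = 0.00241, and adjusted p = 0.181 with an estimated correlation), including GADD45A, a growth arrest gene (38.9-fold), FDXR (8.05-fold), ZMAT3 (6.68-fold) and PLK2 (5.76-fold). Of the unfolded protein and amino acid stress list 13 of 17 fell, with XBP1, a factor of the unfolded protein response, 10.8-fold lower, and 4 rose, with SESN3, a sestrin, 35.5-fold higher (camera adjusted p = 0.0182, and adjusted p = 0.515 with an estimated correlation). The oocyte and zygotic genome activation list fell in all 5 tested genes (camera adjusted p = 0.0182, and adjusted p = 0.436 with an estimated correlation), among them the oocyte growth factor BMP15, which had no read in EPSC and 12.7 ± 2.76 CPM in blastocyst. Among genes that could be named, the largest rises by fitted log2 fold change were in the histone variant MACROH2A2 (at least 707-fold), the cadherin CDH11 (at least 461-fold), the chromatin protein HMGA2 (1258-fold (95% counting interval 430.1 to 6102)), LRRN1 (at least 312-fold) and the hedgehog receptor component SMO (819.7-fold (95% counting interval 280.2 to 3977)). The largest falls among them besides PTGS2 were in HAVCR1, a phosphatidylserine receptor (at least 5274-fold), the organic anion transporter ABCC2 (at least 2593-fold), PRAP1 (8507-fold (95% counting interval 1526 to 336070)) and XPNPEP2, a membrane aminopeptidase (at least 1479-fold). The hypoblast factor GATA6 was 340.2-fold lower. SOX17 was 2.33-fold lower, with adjusted p = 0.0290 that rose to 0.116 without EPSC replicate 1, 0.0747 without EPSC replicate 2, 0.0636 without blastocyst replicate 2 and 0.0575 on FPKM.

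The remaining lists were not called. Hypoblast genes went both ways (8 higher and 11 lower of 19, camera adjusted p = 0.629), as did WNT targets (6 and 4 of 11, adjusted p = 0.680) and TGF-beta family targets (7 and 6 of 17, adjusted p = 0.680). The same held for imprinted genes (12 and 5 of 20, adjusted p = 0.134), integrins and laminins (8 and 14 of 23, adjusted p = 0.113) and neuroectoderm genes (7 and 2 of 14, adjusted p = 0.123). LIF and JAK-STAT genes were higher in 1 and lower in 8 of 15 (adjusted p = 0.0540), and mesoderm and gastrulation genes in 2 and 5 of 11 (adjusted p = 0.702). Germ cell genes were higher in 1 and lower in 3 of 6 (adjusted p = 0.508), interferon response genes in 2 and 5 of 10 (adjusted p = 0.488), and innate immune and blood cell genes in 1 and 4 of 5 (adjusted p = 0.259). The median and mean log2 fold change differed in sign for mesoderm and gastrulation (0.31 and -0.89, test downward) and TGF-beta family targets (0.19 and -0.26, test upward). Counts adjusted over the list alone were the same as these in every list except p53 targets, where 13 fell in place of 12. The call of FGF and ERK targets ended without blastocyst replicate 2 (adjusted p = 0.111) and without EPSC replicate 2 (adjusted p = 0.0501), and LIF and JAK-STAT was called without EPSC replicate 2 (adjusted p = 0.0376), without either iPSC replicate (adjusted p = 0.0475) and under a looser filter (adjusted p = 0.0492). ESRRB, DPPA2, UHRF1, DNMT1, TET2, ETV5, DUSP6, CDH1, ATP1A1, VIM, MMP2, COL3A1, PFKM, PKM, XBP1, SESN3 and BMP15 were chosen after their values were seen. NDUFB9, PKP3, ND4L, ZMAT3, BUB1B, MACROH2A2, LRRN1, SMO and ABCC2 overlap another gene, as do COL3A1, PFKM and UHRF1, and their counts are uncertain because the strand setting of the counting is not given in the sources used here.

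**Figure D2:**
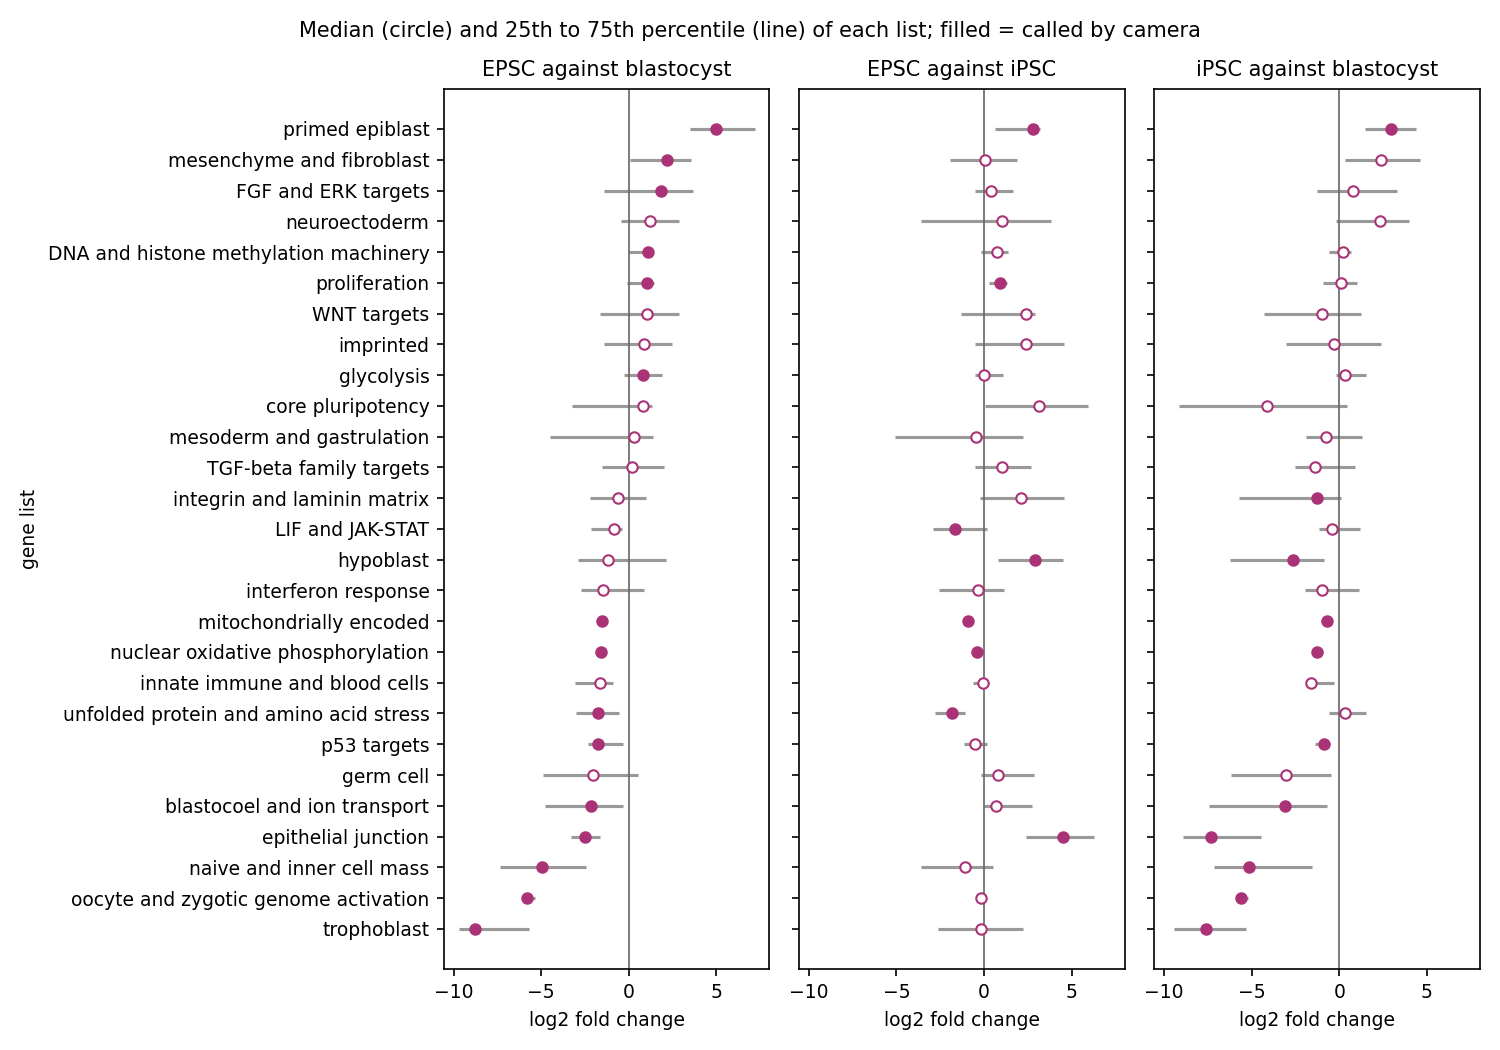
Each circle is the median log2 fold change of the tested genes of 1 of the 27 gene lists fixed before the data were examined, and each line runs from the 25th to the 75th percentile of its genes, in the 3 comparisons. Filled circles are lists called by camera with its preset correlation (15, 8 and 11 lists), and none was called with an estimated correlation.

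The second comparison set the EPSC line against the iPSC line. POU5F1 and LIN28A had 2 of the 5 highest log2 fold changes among genes that could be named. POU5F1 was at least 1113-fold higher in EPSC than in iPSC and LIN28A 1770-fold higher, at 698 ± 6.64 against 0.609 ± 0.862 CPM. All LIN28A reads in iPSC came from a single library. Its fold is a fitted value that departs from the ratio of these means, and its size is uncertain. Epithelial junction genes rose in 22 of 24 and fell in 1 (camera adjusted p = 2.00e-07, and adjusted p = 0.480 with an estimated correlation), and genes of the unfolded protein and amino acid stress list fell in 16 of 17 (camera adjusted p = 5.19e-07, and adjusted p = 0.498 with an estimated correlation).

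Of the 14397 genes, 4913 were higher and 4374 lower in EPSC (limma-voom, Benjamini-Hochberg adjusted p under 0.05), and 2309 higher and 1584 lower against a log2 fold change of 1. The 47 called genes named by the rule had adjusted p between 1.58e-11 and 0.0403 (limma-voom). Core pluripotency genes were higher in 7 and lower in 1 of 13, with a median log2 fold change of 3.12 (camera adjusted p = 0.0514). In iPSC 14 of 38 measured HOX genes lay at a mean of 5 CPM or more, against 0 in EPSC, a count chosen after the values were seen. PRDM14, a repressor that guards pluripotency, was at least 106-fold higher and had no read in iPSC. The exception was NANOG, 3.37-fold lower in EPSC at 4.98 ± 0.938 against 17.5 ± 2.10 CPM. MYC was 2.30-fold lower, and KLF4 2.95-fold lower with adjusted p = 0.0173, which rose to 0.209 without EPSC replicate 1, 0.093 without EPSC replicate 2 and 0.108 without iPSC replicate 1. Naive and inner cell mass genes went both ways, with 2 higher and 5 lower of 11 (camera adjusted p = 0.480).

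Primed epiblast genes rose in 12 of 15 and fell in 2 (camera adjusted p = 8.27e-05, and adjusted p = 0.480 with an estimated correlation). VRTN was 60.4-fold higher, SOX11 34.9-fold higher, the zinc finger factor SALL2 15.2-fold higher and the WNT receptor FZD7 10.2-fold higher. DNMT3B was 7.06-fold higher, at 1835 ± 28.3 against 260.3 ± 20.2 CPM. The epithelial junction list had a median log2 fold change of 4.48, or 4.23 with genes of at most 3 counts in a group set at a bound of 3 counts. SPINT2 and the epithelial transcription factor GRHL2 were at least 185-fold and at least 140.2-fold higher, SPINT1 361-fold higher (95% counting interval 64.4 to 14279) and CLDN6 129.6-fold higher. Hypoblast genes rose in 13 of 19 and fell in 4 (camera adjusted p = 0.0147, and adjusted p = 0.553 with an estimated correlation). The apolipoproteins APOE and APOA1 were 310.2-fold and 291-fold higher, the endoderm factor FOXA2 16.8-fold higher and the basement membrane protein NID2 30.6-fold higher (95% counting interval 10.2 to 151), whereas GATA6, a defining factor of the hypoblast, was 54.9-fold lower. SOX17 was 2.71-fold higher, with adjusted p = 0.0403 and levels of 2.23 ± 0.0816 and 0.763 ± 0.217 CPM, and it did not pass when any EPSC or iPSC replicate was left out (adjusted p = 0.0729 to 0.195). CDX2 had no read in either line, and GATA3 was at 0.561 ± 0.434 and 0.102 ± 0.144 CPM (adjusted p = 0.0879), a value that passed without either blastocyst replicate (adjusted p = 0.0449). Trophoblast genes were higher in 5, lower in 5 and not past the test in 10 of 20 (camera adjusted p = 0.931).

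Genes of the unfolded protein response and amino acid stress had a median log2 fold change of -1.81. The stress factor ATF3 was 16.2-fold lower, the endoplasmic reticulum chaperone DNAJB9 14.2-fold lower, the pseudokinase TRIB3 13.3-fold lower and the cystine transporter SLC7A11 7.24-fold lower. LIF and JAK-STAT genes fell in 10 of 15 and rose in 3 (camera adjusted p = 0.0119, and adjusted p = 0.480 with an estimated correlation). The receptor LIFR was 10.9-fold lower and OSMR 14.8-fold lower, the kinase JAK1 7.81-fold lower, STAT3 7.18-fold lower and the target JUNB 15.7-fold lower. Proliferation genes rose in 21 of 27 and fell in 1 (camera adjusted p = 2.38e-05, and adjusted p = 0.379 with an estimated correlation), including the kinases BUB1 (4.27-fold) and PLK1 (2.92-fold), the ribonucleotide reductase subunit RRM2 (3.69-fold) and topoisomerase TOP2A (3.04-fold). Of the protein-coding genes of the mitochondrial genome 12 fell and 1 rose, with a median log2 fold change of -0.91 (camera adjusted p = 2.31e-05, and adjusted p = 0.503 with an estimated correlation). ATP8 was 5.02-fold lower, COX1 2.45-fold lower, ND4L 2.03-fold lower and ND4 2.01-fold lower. Nuclear genes of oxidative phosphorylation fell in 20 of 34 and rose in 2, with a median log2 fold change of -0.40 (camera adjusted p = 0.0147, and adjusted p = 0.503 with an estimated correlation), and 7.85% of random lists matched on length and expression had a median as low. CYCS was 2.18-fold lower, COX4I1 2.12-fold lower and NDUFB9 1.99-fold lower. NDUFB3 was 2.10-fold lower with adjusted p = 0.0381, and did not pass without EPSC replicate 1 (adjusted p = 0.185), EPSC replicate 2 (adjusted p = 0.114) or iPSC replicate 1 (adjusted p = 0.185).

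Besides POU5F1 and LIN28A, the largest rises among genes that could be named were in SHISA2, an inhibitor of FGF and WNT receptor maturation (at least 643-fold), the receptor phosphatase PTPRK (at least 494-fold) and ISYNA1, an enzyme of inositol synthesis (at least 490.3-fold), none of which had a read in iPSC. The largest falls among them were in the transcription factor TFAP2D (ENSSSCG00000001744, chromosome 7, 44640078 to 44702561, plus strand, at least 1486-fold), the steroid dehydrogenase HSD17B2 (5165-fold (95% counting interval 927 to 204060)), the membrane protein EMP1 (at least 865-fold), the smooth muscle actin ACTG2 (at least 623-fold) and the cytokine IL16 (at least 612-fold). The lists of other cell types were not called. Mesenchyme and fibroblast genes were higher in 6 and lower in 7 of 17 (camera adjusted p = 0.850), neuroectoderm genes in 7 and 5 of 14 (adjusted p = 0.464), and innate immune and blood cell genes in 1 and 1 of 5 (adjusted p = 0.875). Not called either were mesoderm and gastrulation (3 higher and 5 lower of 11, adjusted p = 0.480), germ cell (3 and 1 of 6, adjusted p = 0.579) and oocyte and zygotic genome activation genes (0 and 0 of 5, adjusted p = 0.747). The list of DNA and histone methylation machinery was higher in 13 and lower in 5 of 21 (adjusted p = 0.0514), imprinted genes in 11 and 5 of 20 (adjusted p = 0.198), and integrins and laminins in 12 and 6 of 23 (adjusted p = 0.198). Signalling targets split without a call: WNT targets 7 higher and 4 lower of 11 (adjusted p = 0.480), FGF and ERK targets 8 and 5 of 17 (adjusted p = 0.492), and TGF-beta family targets 8 and 4 of 17 (adjusted p = 0.280). So did blastocoel and ion transport (9 and 2 of 15, adjusted p = 0.204), p53 targets (4 and 8 of 17, adjusted p = 0.188), interferon response (1 and 3 of 10, adjusted p = 0.439) and glycolysis genes (9 and 8 of 20, adjusted p = 0.850). The median and mean log2 fold change differed in sign for mesenchyme and fibroblast (0.08 and -0.08, test downward) and glycolysis (-0.01 and 0.31, test upward). Counts adjusted over the list alone were the same as these in every list. Core pluripotency was called without EPSC replicate 2 (adjusted p = 0.0476) and the methylation machinery without iPSC replicate 2 (adjusted p = 0.0349). PRDM14, FOXA2 and STAT3 were chosen after their values were seen. GRHL2, CLDN6, ATP8, ND4L, ND4, PLK1, JUNB, OSMR, LIFR, COX4I1, NDUFB9, PTPRK and ISYNA1 overlap another gene, so their counts are uncertain for the reason given above.

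The third comparison set the iPSC line against cloned blastocysts. POU5F1 was at least 631-fold lower in iPSC and LIN28A 788-fold lower, a fitted fold of uncertain size because a single iPSC library held all LIN28A reads. The trophoblast and epithelial junction lists had the lowest medians of the 27 lists. Epithelial junction genes fell in 23 of 24 (camera adjusted p = 1.64e-10, and adjusted p = 0.236 with an estimated correlation) and trophoblast genes in all 20 tested (camera adjusted p = 3.55e-08, and adjusted p = 0.206 with an estimated correlation). Primed epiblast genes rose in 13 of 15 (camera adjusted p = 1.26e-04, and adjusted p = 0.236 with an estimated correlation), and NANOG was 2.97-fold higher in iPSC, at 17.5 ± 2.10 against 5.82 ± 0.573 CPM.

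Of the 14397 genes, 4972 were higher and 5432 lower in iPSC (limma-voom, Benjamini-Hochberg adjusted p under 0.05), and 2603 higher and 2906 lower against a log2 fold change of 1. On the deposited FPKM the split was 5991 higher and 4029 lower, or 59.8% higher against 47.8% on counts, with the median of all genes 0.256 higher in log2 fold change. The FPKM lacked TMM scaling, whose factors were 1.10 and 1.09 in iPSC and 0.814 and 0.793 in blastocyst. The 50 genes named by the rule and tested had adjusted p between 5.35e-10 and 0.00237 (limma-voom). The epithelial junction list had a median log2 fold change of -7.31, or -6.97 with genes of at most 3 counts in a group set at a bound of 3 counts. SPINT1 (ENSSSCG00000004759, chromosome 1, 130458909 to 130473783, minus strand) was 8933-fold lower (95% counting interval 1603 to 352890), SPINT2 at least 931-fold lower, CLDN7 at least 495-fold lower and the epithelial splicing factor ESRP2 1737-fold lower (95% counting interval 311 to 68661). The trophoblast list had a median log2 fold change of -7.60, or -7.43 at the bound. The keratin KRT18 was 4492-fold lower, from 8701 ± 406 to 2.47 ± 2.34 CPM, the endocytic adaptor DAB2 2076-fold lower, GATA3 3557-fold lower (95% counting interval 638 to 140520), the homeobox factor MSX2 at least 478-fold lower and CDX2 at least 276-fold lower. Blastocoel and ion transport genes fell in 12 of 15 and rose in 3 (camera adjusted p = 0.00636, and adjusted p = 0.236 with an estimated correlation). The water channels AQP3 and AQP9 were at least 658-fold and 979-fold (95% counting interval 175 to 38702) lower, the sodium channel subunit SCNN1A 412-fold lower (95% counting interval 141 to 2002) and the phosphate transporter SLC34A2 408-fold lower. Integrin and laminin matrix genes fell in 16 of 23 and rose in 4 (camera adjusted p = 0.0220, and adjusted p = 0.505 with an estimated correlation), among them ITGA5, the fibronectin receptor subunit (108-fold), and LAMB3, a chain of epithelial laminin (at least 239-fold).

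Hypoblast genes fell in 14 of 19 and rose in 3 (camera adjusted p = 0.00635, and adjusted p = 0.505 with an estimated correlation). APOA1 was 993-fold lower, APOC3 at least 68.7-fold lower, and the endoderm factors GATA4 and HNF4A 231-fold (95% counting interval 63.7 to 1917) and at least 32.4-fold lower. GATA6 was 6.20-fold lower and SOX17 6.31-fold lower. Naive and inner cell mass genes fell in 8 of 11 and rose in 2 (camera adjusted p = 0.0217, and adjusted p = 0.505 with an estimated correlation), with KLF5, a factor of early embryo cells, 116-fold lower and KLF4 10.4-fold lower. MYC was 1.98-fold lower. Core pluripotency genes were higher in 3 and lower in 8 of 13 (camera adjusted p = 0.0904). In the primed epiblast list SFRP2 was at least 204-fold higher, SFRP1 24.2-fold higher, the zinc finger factor ZIC3 33.4-fold higher, the neural cadherin CDH2 27.1-fold higher and DNMT3B 2.52-fold higher. The oocyte and zygotic genome activation list fell in 4 of 5 genes (camera adjusted p = 0.0378, and adjusted p = 0.505 with an estimated correlation), a call that ended without iPSC replicate 2 (adjusted p = 0.0572).

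Nuclear genes of oxidative phosphorylation fell in 31 of 34 and rose in 1, with a median log2 fold change of -1.26 (camera adjusted p = 2.74e-08, and adjusted p = 0.236 with an estimated correlation). ATP5MC1 was 5.27-fold lower, ATP5F1A, the catalytic core subunit alpha of ATP synthase, 3.58-fold lower, and the complex subunits UQCRC1 and NDUFS3 3.37-fold and 3.23-fold lower. Of the protein-coding genes of the mitochondrial genome 12 fell and 1 rose (camera adjusted p = 1.29e-04, and adjusted p = 0.505 with an estimated correlation): CYTB was 3.32-fold lower, ND6 2.8-fold lower and ND3 2.11-fold lower, while ATP8 was 2.23-fold higher. Of the p53 targets 13 of 17 fell and 2 rose (camera adjusted p = 0.0217, and adjusted p = 0.281 with an estimated correlation), with GADD45A 12.6-fold lower, FDXR 6.82-fold lower, PHLDA3 6.80-fold lower and PLK2 3.46-fold lower. The largest rises among genes that could be named were in CDH11 (ENSSSCG00000002795, chromosome 6, 25783595 to 25933634, minus strand, at least 2162-fold), TFAP2D (at least 1323-fold), the calcium-binding protein CALB2 (at least 1193-fold), complement factor CFH (at least 691-fold) and the neuronal membrane protein GPM6A (at least 639-fold), none of which had a read in blastocyst. The largest falls among them besides SPINT1 were in the nucleoside transporter SLC28A3 (at least 8899-fold), HAVCR1 (at least 4518-fold), PRAP1 (at least 2430-fold) and the surface antigen TACSTD2 (at least 1637-fold), with no read in iPSC.

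The other lists were not called. Mesenchyme and fibroblast genes were higher in 9 and lower in 4 of 17 (camera adjusted p = 0.0632), neuroectoderm genes in 9 and 3 of 14 (adjusted p = 0.217) and glycolysis genes in 13 and 6 of 20 (adjusted p = 0.0819). Mesoderm and gastrulation genes gave 4 higher and 3 lower of 11 (adjusted p = 0.844), germ cell genes 1 and 3 of 6 (adjusted p = 0.321), and innate immune and blood cell genes 1 and 3 of 5 (adjusted p = 0.465). Imprinted genes gave 9 higher and 9 lower of 20 (adjusted p = 0.898), the methylation machinery 8 and 7 of 21 (adjusted p = 0.714), and proliferation 13 and 10 of 27 (adjusted p = 0.609). WNT targets gave 3 higher and 5 lower of 11 (adjusted p = 0.717), FGF and ERK targets 9 and 7 of 17 (adjusted p = 0.376), TGF-beta family targets 7 and 9 of 17 (adjusted p = 0.606) and LIF and JAK-STAT 6 and 7 of 15 (adjusted p = 0.717). Genes of the unfolded protein response and amino acid stress gave 8 higher and 6 lower of 17 (adjusted p = 0.557), and interferon response genes 2 and 4 of 10 (adjusted p = 0.839). The median, mean and test differed in sign for mesoderm and gastrulation (median -0.74, mean 0.06, test upward), imprinted (median -0.32, mean -0.99, test upward), LIF and JAK-STAT (median -0.41, mean -0.03, test upward) and proliferation genes (median 0.12, mean -0.06, test upward). Counts adjusted over the list alone were the same as these except that 7 stress genes fell in place of 6 and 9 genes of the methylation machinery rose in place of 8. Without blastocyst replicate 2, core pluripotency and the mesenchyme list (both adjusted p = 0.0443) and glycolysis (adjusted p = 0.046) were called. ITGA5, LAMB3 and KLF5 were chosen after their values were seen. ESRP2, NDUFS3, KRT18, DAB2, ND6, ATP8, APOC3, AQP9, SCNN1A, CFH and GPM6A overlap another gene, and their counts are uncertain in the same way.

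Both lines moved the same way from blastocyst in many genes: 3156 were higher in EPSC and in iPSC, and 3836 lower in both. CDH11, SFRP1 and SFRP2 were among those higher and GATA3, CDX2, HAVCR1 and PRAP1 among those lower. Independent lists of these sizes would share 1843.5 higher and 1980.5 lower genes. In 20 simulations all libraries were drawn at the blastocyst level, so that unchanged lines shared simulated blastocyst libraries. These simulations gave a mean of 0 and 0 shared genes. That is no reference for the shared counts, since unchanged lines give few calls of any kind. Against a log2 fold change of 1, 3239 genes moved the same way in both lines. Pearson's r of the 2 sets of fold changes across genes was 0.654, against 0.511 in the simulations, and their covariance 5.23 against 0.0932, a difference of 5.14. The sign was the same in 74.2% of the genes, against 66.6% simulated. With 2 blastocyst libraries the controls were not split, as each part would hold 1 library, and part of the excess may come from sharing them. All 20 tested trophoblast genes fell in both lines, and how far cells of the embryo that both lines lack account for the shared genes was not tested.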

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

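The tests of POU5F1 and LIN28A, the choice of COL1A1, COL5A1, FBN1 and TIMP1 as examples and the test of correlated departures of FPKM from counts were chosen after the result was seen.

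The lines moved in opposite directions from blastocyst in 1 set of genes each way. In 626 genes EPSC was above blastocyst and iPSC below it, and in 526 genes the reverse held. By comparison, 3156 genes were higher and 3836 lower in both lines. All genes of these opposite sets also differed in the direct test of EPSC against iPSC. That adds little, since in the same fit the direct comparison is the difference of the others. POU5F1 and LIN28A belong to the first set. Their near absence in iPSC is not one of depth, since at the EPSC level 3338 POU5F1 reads would be expected in the iPSC libraries and 0 were found. Fibroblasts in place of the whole line are argued against, since their abundant collagens and proteoglycans COL1A1, COL1A2, COL3A1, LUM and DCN summed to 14.0 CPM in iPSC. The mesenchyme and fibroblast list went both ways, with 6 higher and 7 lower of 17 in EPSC against iPSC (camera adjusted p = 0.850), among them COL1A1 (49.8 against 1.53 CPM) and COL5A1 (109 against 0.445 CPM) higher and FBN1 (65.9 against 257 CPM) and TIMP1 (7.60 against 359 CPM, a gene that overlaps another) lower, and mesenchymal cells of another kind stay open. As a hypothesis, the cells labelled iPSC may have left the pluripotent state: 36.8% of the measured HOX genes (14 of 38) lay at 5 CPM or more in iPSC, against 0 in EPSC and 4 in blastocyst. NANOG, higher in iPSC, goes against a general loss of the network, and other cells under that label or reads of a reprogramming transgene that do not match the pig gene were not tested and stay open, as does a difference between the lines themselves.

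Counts and FPKM parted in the EPSC libraries. In EPSC 546 and 531 genes had no read and an FPKM above 0, against 12 and 15 in blastocyst and 7 and 10 in iPSC. Another use of isoforms is argued against, since among 1259 genes with 1 annotated transcript the spread of the length implied by counts and FPKM, relative to blastocyst, was 30.001 times as wide in EPSC as in iPSC (0.330 against 0.011 on the log2 scale), although over all 6031 genes compared the ratio was 1.57 (0.216 against 0.138). Reads of overlapping genes assigned differently are argued against too, with a ratio of 39.3 in 732 such genes with no overlapping gene. Different runs of the processing behind the EPSC values of the 2 tables stay open. The departures correlated across genes between the EPSC libraries (Pearson's r 0.549 over the 732 genes, which are not independent replicates, against 0.217 in iPSC, and 0.686 against 0.713 over all 6031), but any cause that acts alike on both libraries, and the shared blastocyst reference, would give that. No biological explanation other than isoform use was tested, and which table is nearer to the RNA stays open.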

How the results depend on the processing

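The tests with limma-trend on log2 CPM, a filter of a mean of 5 CPM and nuclear protein-coding genes only were chosen after the result was seen.

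Each count of genes of 1 comparison had 14 alternatives besides leaving out replicates, and under 12 or 13 of them it stayed within 1.5 times the main count, as the count for both lines did under 6 of 7. The exceptions were the test against a log2 fold change of 1, a stricter question, and FPKM. Against a log2 fold change of 1, 5592 genes changed in EPSC against blastocyst (2961 higher, 2631 lower), 3893 in EPSC against iPSC (2309 higher, 1584 lower), 5509 in iPSC against blastocyst (2603 higher, 2906 lower) and 3239 in both lines. With limma-trend on log2(FPKM + 1) and a mean FPKM of 1, 3280 genes were lower in EPSC and 3527 in iPSC, each against blastocyst, over 12393 genes. The FPKM lacked the TMM scaling of the counts, and leaving it out works toward fewer lower genes in both lines. How much of the difference it makes up was not tested. FPKM moved the median log2 fold change of all genes by 0.352, 0.081 and 0.256, and median-of-ratios scaling by at most 0.032. The filter planned as stricter proved looser, with 15616 genes. The planned DESeq2 alternative was not run, because the cells written with commas failed a check of the count unit.

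Of the 27 lists, the estimated correlation called 0 in each comparison and fry, which compares a list with no other genes, 23, 19 and 23. The mean distance between groups was 5.03 with the top 2000 genes of each pair and 5.11 on log2(FPKM + 1), in both cases by construction over other genes or values. Leaving out 1 replicate, where the lone library is assumed to vary like the other groups, gave 8996 to 10546 genes for EPSC against blastocyst (higher 4608 to 5306, lower 4388 to 5240), 7233 to 9529 for EPSC against iPSC (higher 3998 to 5031, lower 3235 to 4498), 9397 to 10030 for iPSC against blastocyst (higher 4558 to 4823, lower 4839 to 5245) and 6121 to 6594 for both lines. Lists called ran from 14 to 16, 8 to 9 and 10 to 14. On FPKM the median of imprinted genes in iPSC against blastocyst turned from -0.32 to 0.15 and that of glycolysis in EPSC against iPSC from -0.01 to 0.15, neither list called, beside medians of all genes that moved from -0.06 to 0.20 and from 0.04 to 0.12.

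Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at -0.022, -0.020 and 0.024 across genes. With the replicate block, 10613 genes changed in EPSC against blastocyst (5341 higher, 5272 lower), 9360 in EPSC against iPSC (4946 higher, 4414 lower), 10352 in iPSC against blastocyst (4946 higher, 5406 lower) and 7003 in both lines, with 14, 9 and 11 lists. The block took the call from FGF and ERK targets in EPSC against blastocyst (adjusted p = 0.0627) and gave one to core pluripotency in EPSC against iPSC (adjusted p = 0.0483) and to GATA3 there (adjusted p = 0.0479). Genes named, or chosen after their values were seen, were followed over 12 of the alternatives. The test against a log2 fold change of 1 was not among them. No such gene reversed over 919, 765 and 764 values of 1 gene under 1 alternative. Of these values 4, 10 and 0 lost the call (SOX17 in EPSC against blastocyst, and NDUFB3, KLF4 and SOX17 in EPSC against iPSC). Another 0, 3 and 0 gained one (GATA3). Depth limits low genes: 3 counts stood for 0.762 TMM-scaled CPM in the shallowest library.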

Other observations

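The tests of all gene lists in this part other than trophoblast, epithelial junction and oxidative phosphorylation, and the test of the 50 most abundant genes, were chosen after the result was seen, while the test of oxidative phosphorylation with length-matched lists was not. All genes named in this part were chosen after their values were seen. Lysosomal genes were lower in both lines than in blastocyst: 34 of 39 fell and 4 rose in EPSC, with a median log2 fold change of -3.55 (camera adjusted p = 1.35e-10, and adjusted p = 0.145 with an estimated correlation). The protease CTSD was 136-fold lower in EPSC and the saposin precursor PSAP 89.5-fold lower, while GM2A, a ganglioside activator, was 212-fold lower. All 17 tested genes of the vacuolar proton pump fell in EPSC (camera adjusted p = 8.85e-09, and adjusted p = 0.135 with an estimated correlation), and ATP6V0A4, its membrane subunit, was 1556-fold lower (95% counting interval 532 to 7550). In iPSC 31 lysosomal genes fell and 3 rose (camera adjusted p = 1.19e-08, and adjusted p = 0.183 with an estimated correlation), as did 16 and 1 pump genes (camera adjusted p = 3.99e-07, and adjusted p = 0.166 with an estimated correlation), with CTSD 127-fold lower and PSAP 74.0-fold lower. Beside this and the lists that follow, all 20 tested trophoblast genes were lower than in blastocyst in both lines (median log2 fold change -8.76 in EPSC and -7.60 in iPSC). Between EPSC and iPSC, 8 lysosomal genes were higher and 16 lower (camera adjusted p = 0.255, 13 lower adjusted over the list alone), with a median of -0.28 and a mean of 0.09 (test downward), and 3 pump genes rose and 8 fell (camera adjusted p = 0.0469, and adjusted p = 0.493 with an estimated correlation), a call that median-of-ratios scaling ended (adjusted p = 0.0504). CTSD, PSAP, GM2A and ATP6V0A4 overlap another gene and their counts are uncertain. For the other later lists, counts adjusted over the list alone were the same as over all genes.

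Hedgehog pathway genes rose in 10 of 12 in EPSC against blastocyst (camera adjusted p = 8.38e-04, and adjusted p = 0.135 with an estimated correlation), with the transcription factor GLI2 192-fold higher and the receptor PTCH1 6.60-fold higher. In iPSC against blastocyst 11 rose (camera adjusted p = 5.58e-05, and adjusted p = 0.166 with an estimated correlation), with GLI2 247-fold higher and PTCH1 10.8-fold higher, and between the lines 3 were higher and 6 lower (camera adjusted p = 0.333). Of 25 collagens 18 rose and 4 fell in EPSC against blastocyst (camera adjusted p = 0.00116, and adjusted p = 0.135 with an estimated correlation), with COL2A1 708-fold higher and COL18A1 14.6-fold higher. Against iPSC 15 rose and 6 fell (camera adjusted p = 0.0353, and adjusted p = 0.187 with an estimated correlation), with COL2A1 419-fold higher, and in iPSC against blastocyst 10 were higher and 7 lower (camera adjusted p = 0.296). HOX genes, positional regulators of the body axis, rose in 19 of 24 and fell in 3 in iPSC against blastocyst (camera adjusted p = 2.66e-04, and adjusted p = 0.166 with an estimated correlation), with HOXA9 32.7-fold higher and HOXB13 51.3-fold higher, both of which overlap another gene. They fell in 15 in EPSC against blastocyst (camera adjusted p = 0.0147, and adjusted p = 0.237 with an estimated correlation) and in 22 in EPSC against iPSC (camera adjusted p = 3.84e-08, and adjusted p = 0.113 with an estimated correlation). The basal keratin KRT5 was 78.3-fold higher in iPSC against blastocyst and NAV3 and DCLK1 110.4-fold and 314-fold higher, while TKTL1, a transketolase-like enzyme, was at least 196-fold lower.

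Ribosomal protein genes fell in 51 of 63 and rose in 3 in EPSC against blastocyst (camera adjusted p = 3.41e-07, and adjusted p = 0.135 with an estimated correlation), by a median of -0.38 that turned to 0.17 on FPKM, where the median of all genes was 0.37, and lay at percentile 93.4 of lists matched on transcript length and expression, above their median of -0.64. Against iPSC 60 fell (camera adjusted p = 3.38e-20, and adjusted p = 0.113 with an estimated correlation, percentile 0 of matched lists), and in iPSC against blastocyst 42 rose and 4 fell (camera adjusted p = 7.15e-07, and adjusted p = 0.166 with an estimated correlation, percentile 100 of matched lists). Sterol synthesis genes rose in 15 of 23 and fell in 4 in iPSC against blastocyst (camera adjusted p = 0.00616, and adjusted p = 0.275 with an estimated correlation), with HMGCR, the enzyme that controls sterol synthesis, 2.31-fold higher. In EPSC 12 were higher and 5 lower than in blastocyst (camera adjusted p = 0.123) and 2 and 11 against iPSC (adjusted p = 0.0541). Notch pathway genes gave 9 higher and 4 lower of 17 in EPSC against blastocyst (camera adjusted p = 0.151), 7 and 7 against iPSC (adjusted p = 0.970, median 0.12 and test downward) and 7 and 5 in iPSC against blastocyst (adjusted p = 0.367, median -0.20, mean 0.44 and test upward).

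The fall of nuclear genes of oxidative phosphorylation in EPSC against blastocyst was weighed against technical explanations. A lower recovery of short transcripts is argued against as the whole cause, since the list median of -1.56 lay at percentile 0.01 of lists matched on transcript length and expression, although the median of those lists, -0.49, was also below 0. A few abundant genes taking counts in EPSC are argued against too, since the 50 most abundant genes of each library held 14.0% of its counts in EPSC (mean of 2 libraries) and 22.4% in blastocyst. All 20 tested trophoblast genes and 21 of 24 epithelial junction genes fell in the same comparison, so that cells of the embryo which the line lacks, and a difference in metabolism between them, both stay open and were not tested.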
